A study of Mus musculus with 96 samples.

How the data were processed

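The samples were 96 total RNA preparations from 8 tissues of DBA/2J mice on a standard breeding diet or a high-fat diet, with 6 biological replicates per tissue and diet. Per the labels, RNA was extracted with TRIzol Plus, its quality was read on a Bioanalyzer, and biotin-labelled cRNA was hybridized to Illumina Mouse-6 BeadChips. Dissections were spread over successive days, but the labels do not give the day of an animal, the chip or the position of an array.

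The authors deposited a table of non-normalized signal intensity, with 1 value per probe and array for 46632 probes; per the file headers no detection p-value came with it. Its values were linear, from 11.76 to 71625.1, with array medians from 107.4 to 244.4. The scanner software, the background handling and the summary of beads were not given in the sources used here. The authors also deposited a table of log2 values for the same arrays, whose normalization the labels do not state. It was checked against the intensities: the sorted values of every array equalled the mean over the 96 arrays of the sorted log2 intensities to within 0.00191, each array had a median of 7.391, and the rank correlation with the same sample's non-normalized column was 1. The log2 values were therefore those of a quantile normalization over all arrays without background correction. Every value column was matched to a sample by its label (0 were left over). The highest correlation of log2 signal between any 2 arrays was 0.99554, so no array was a copy of another, and the lowest within a group was 0.94204.

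Values were computed from the intensities. Within the 12 arrays of a tissue the background was modelled with limma's normexp method with an offset of 50, log2 was taken and the arrays were quantile normalized. The design asked first for the background model that uses detection p-values, and this was its stated fallback. Without detection p-values, probes were kept when their mean log2 intensity in the tissue lay above the median of all probes. Gene symbols came from the platform's probe table, updated by Entrez number to a reference gene table (assembly GRCm38.p6, used for names only). Of the 46632 probes 29976 had 1 symbol, 10 had several and 16646 had none; 29921 probes matched the reference table. For each of the 17711 genes named the probe with the highest mean over all arrays was kept, and probes without a symbol stayed in the tests, which left 34367 genes or unnamed probes before the filter. No coordinates are given.

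Differences between diets were tested within each tissue with limma (version 3.58.1 in R 4.3.3), as a two-sided moderated test of 6 against 6 arrays with no covariate, and p-values were adjusted by the Benjamini-Hochberg method over all genes and unnamed probes tested in the tissue. A gene was called at an adjusted p under 0.05. The values of all tissues were joined for 4 further limma tests with 1 mean per tissue and diet: whether the diet effect differed between the 8 tissues, between the 5 white depots, or between the intra-abdominal and the subcutaneous white depots, and the mean effect over the 8 tissues. For the comparison of depots on the standard diet the 60 white fat arrays were normalized together. In each tissue 29 to 32 of 33 lists of genes had at least 5 measured members and were tested with limma's camera with a preset correlation of 0.01 between genes, adjusted over the lists of the tissue. The correlation was also estimated from the data. The design, the lists, the rule for the genes to name and the alternative settings named next were made before the data were examined.

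By that rule, the genes named in a tissue come from the 12 largest rises and the 12 largest falls among called genes with an official symbol. Where fewer than 5 passed in a direction, the next by unadjusted p filled up to 5 and are said not to pass. To these were added, for each list whose shift passed, the 4 members with the smallest p, and in every tissue Lep, Ucp1, Scd1, Fasn, Pdk4 and Mest. For the joint tests the rule took the 10 genes with the smallest p, and for the depot comparison the measured members of a list of positional genes. Not every gene that the rule admits is printed. Of the genes called in all fat tissues, and of the brown fat and adipocyte genes set beside Ucp1 and Lep, those printed were chosen after their values were seen.

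These settings replaced 1 choice at a time: the authors' deposited values, no background correction with signals floored at 16, median scaling in place of quantile normalization, no filter on dim probes, all probes of a gene, all 96 arrays in 1 fit, array weights, the replicate number as a block, a fold change of at least 1.5, each array or tissue left out in turn, and, for the joint tests, the same diet and number across tissues as a random block. Array brightness as a covariate, a term for the dim arrays, the bright arrays alone, and the number groups of muscle as a term were added after the data had been seen. Of the tests of explanations, also made after the data had been seen, 2 replaced earlier ones. A sign test of the calls that ended with the brightness covariate was dropped, since simulation showed that it would give the same answer under either cause. For brown fat carried into white depots, the medians of 11 other brown fat genes (at most 0.09) had been read alone, without the levels of these genes in brown fat. The share that Ucp1 needs replaced that reading, with its rule set when the values were in view. It was computed first with each tissue normalized alone (smallest shortfall 1.03) and then, as reported, with the fat arrays normalized together. A condition that at most 1 of the 11 genes be called higher, which had left inguinal fat open, was then dropped, so that all 4 depots are read by the same bound. Brightness was the log2 ratio of an array's upper-quartile to its median signal. Other splits of the samples were drawn 100 times at random from the 462 ways to split 12 animals 6 against 6, the same numbers in every tissue for the joint tests, and the 10 ways to split 5 depots were all run. One gene's several probes were compared too: of the other probes of called genes, 981 in brown, 753 in gonadal, 1506 in inguinal, 42 in mesenteric, 1618 in perirenal and 1283 in subcutaneous fat, 99 in liver and 10 in muscle, those called the same way numbered 209, 186, 391, 5, 510, 295, 26 and 1 and those called the opposite way 12, 8, 41, 0, 30, 38, 0 and 0. Those with the same sign, called or not, numbered 702, 591, 1078, 32, 1235, 914, 84 and 8.

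The scripts were tested on simulated data in which 200 genes per tissue were changed by known folds. Of genes changed 4-fold, 98.5% were recovered in brown, 100% in gonadal, 100% in inguinal, 97% in mesenteric, 97% in perirenal and 100% in subcutaneous fat, 100% in liver and 98.5% in muscle. At 1.5-fold the shares were 77.6%, 71.6%, 71.6%, 58.2%, 56.7%, 73.1%, 97% and 95.5% in the same order, and 5.7%, 6.8%, 4.3%, 5.7%, 2.9%, 4.7%, 6.6% and 5.8% of the calls were false. The test between the 8 tissues recovered 98.7% of genes changed 4-fold in a tissue and the test between 5 depots 97.9%, with 14.4% and 11.4% false calls; the contrast of depots recovered 92.4% and the mean effect 92%, with 3.5% false calls each. All 8 planted lists of 20 genes changed 1.5-fold were called, and 0 unchanged lists. Draws were independent, so the shares of false calls do not cover correlated genes or arrays, or dim arrays. Simulated brightness with no diet effect gave 0 calls in each fat tissue without a brightness term. On the real arrays, splits not by diet gave a median of 49 list shifts.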

Results

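Messenger RNA was measured in 8 tissues of DBA/2J mice, an inbred laboratory strain, after 6 weeks on either a standard breeding diet or a high-fat diet. The mice were 12 weeks old and had been fasted for 2 hours before dissection. The tissues were brown fat, the heat-producing fat; 5 white fat depots (gonadal, mesenteric and perirenal fat from inside the abdomen, inguinal and subcutaneous fat from under the skin); liver; and skeletal muscle. Each tissue and diet was represented by 6 arrays, so there were 16 groups and 96 arrays. Differences are given as log2 of the high-fat diet over the standard diet, and the value after ± is the standard error with n = 6 arrays per diet unless stated otherwise. The number of arrays limits the precision of every value. The arrays differed in brightness: in each of the 6 fat tissues the 4 dimmest arrays were high-fat replicates 3 to 6. In gonadal fat, for example, the ratio of the upper-quartile to the median signal was 1.55 to 1.72 on these arrays, 1.98 to 2.35 on the standard-diet arrays and 2.51 to 2.65 on high-fat replicates 1 and 2. The labels name no array batch, so each fat tissue's count is followed by the count with brightness as a covariate, the count with a term for the 4 dim arrays, and the count over the bright arrays alone. These fits were added after the data had been seen. Where the mean on 1 diet lay near background, as for Tph2 on the standard diet in brown fat (6.37), the size of the fold depends on the background offset. In liver the ratio was 1.27 to 1.35 on standard-diet arrays and 1.25 to 1.36 on high-fat arrays. In muscle it was 1.35 to 1.39 and 1.3 to 1.37, with means of 1.37 and 1.34 (two-sided exact permutation p = 0.041, 0.24 adjusted over the 8 tissues). Between the diets as a whole the mean brightness of the fat tissues did not pass this test (exact permutation p = 0.061 to 0.21, adjusted 0.24 in each), since replicates 1 and 2 were not among the dim arrays.

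**Figure D1:**
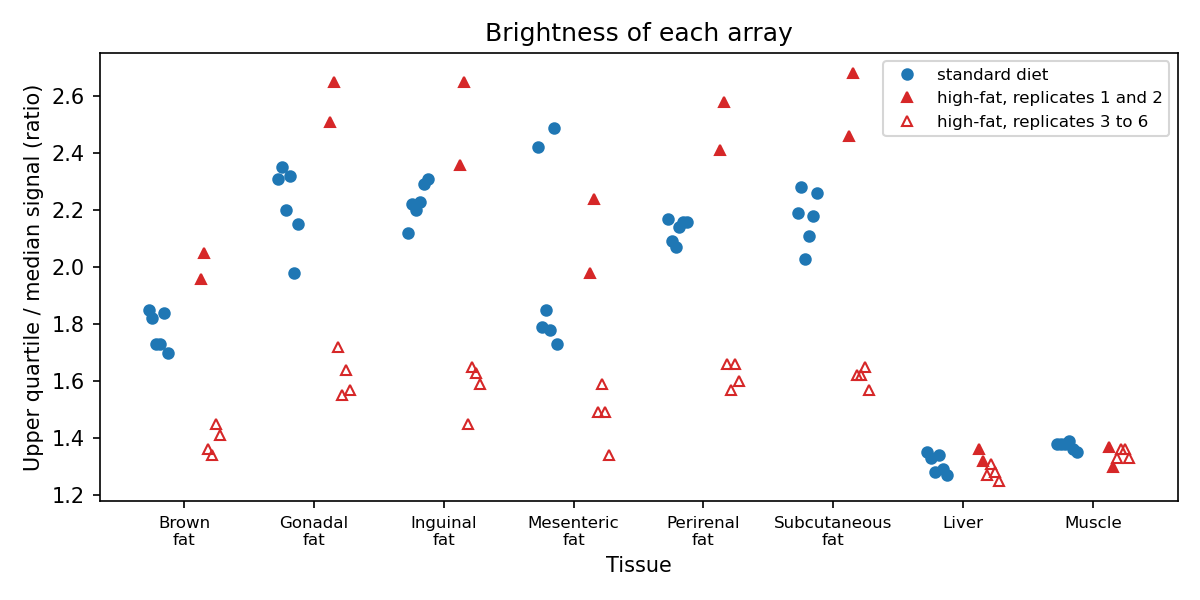
Brightness of each array, as the ratio of its upper-quartile to its median non-normalized signal, in the 8 tissues; circles are standard-diet arrays, filled triangles are high-fat replicates 1 and 2, and open triangles are high-fat replicates 3 to 6. In every fat tissue the 4 open triangles are the lowest points (1.34 to 1.45 in brown fat), while the groups overlap in liver and muscle (means 1.37 and 1.34 in muscle).

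Brown fat on the high-fat diet had less mRNA of several sterol and fatty acid synthesis enzymes and more of several inflammatory and matrix genes. Cyp2e1, a cytochrome P450 that oxidises ethanol and ketone bodies, fell by 3.43 ± 0.28, from a mean log2 intensity of 12.97 (SD 0.69, n = 6) to 9.54 (SD 0.48, n = 6), which is 10.8-fold. Tjp3, a tight junction protein, fell by 1.7 ± 0.13, and Pth1r, the parathyroid hormone receptor, fell by 1.51 ± 0.12. Of 18 measured cholesterol synthesis genes 10 fell and 1 rose (adjusted over the list alone, 12 fell and 1 rose), among them Fdps (-0.9 ± 0.11), Sqle (-0.89 ± 0.11) and Insig1 (-0.95 ± 0.11), which retains the sterol sensor in the endoplasmic reticulum. Of 20 fatty acid synthesis genes 11 fell and 1 rose (12 and 1 adjusted over the list alone), with Slc25a1, the mitochondrial citrate carrier, at -1.14 ± 0.11 and Acss2 at -1.13 ± 0.11. The genes that rose most included Tph2, a tryptophan hydroxylase (2.76 ± 0.37), Ubd, a ubiquitin-like protein induced by cytokines (2.43 ± 0.34), Lcn2, an acute-phase lipocalin (2.04 ± 0.21), and Npr3, the natriuretic peptide clearance receptor (1.79 ± 0.1). Of 18 macrophage markers 16 rose (18 adjusted over the list alone), with Mmp12 at 1.99 ± 0.25 and Mpeg1 at 1.43 ± 0.2. Extracellular matrix genes (16 of 29 rose; 19 adjusted over the list alone), cytokines and acute-phase genes (8 of 16 rose and 1 fell; 9 and 1 adjusted over the list alone) and MHC class II genes (5 of 6 rose; 6 adjusted over the list alone) shifted upward too, with Lox, which cross-links collagen, at 0.76 ± 0.08 and the chemokine Cxcl1 at 1.22 ± 0.08. With brightness as a covariate 10 cholesterol synthesis and 7 fatty acid synthesis genes fell, and 10 macrophage, 8 matrix, 8 cytokine and acute-phase and 4 MHC class II genes rose. These 6 list shifts passed in limma's camera test with adjusted p from 3.59e-14 to 1.01e-05. None passed with an estimated correlation between genes (adjusted p = 0.106 to 0.159 with an estimated correlation). For every gene named here all 6 high-fat arrays lay beyond all 6 standard-diet arrays, with limma adjusted p from 8.22e-08 to 0.000433. In limma's test 2712 of 18079 genes or unnamed probes passed an adjusted p of 0.05, 1220 higher and 1492 lower, or 45% higher (33.3% of 99 under median scaling and 69.3% of 521 with a fold of at least 1.5). The count was 1176 with brightness as a covariate, 178 with a term for the dim arrays (56.7% higher) and 70 over the bright arrays alone (60% higher). Leaving out 1 array gave 1530 without high-fat replicate 5, 1573 without 6, 1645 without 4, 1763 without 3, 1787 without standard-diet replicate 1 and 4124 without high-fat replicate 2.

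Gonadal fat had more mRNA of several inflammatory and matrix genes and less of several lipogenic genes. Tph2 rose by 4.62 ± 0.32 (24.7-fold), Ubd by 3.28 ± 0.28, the leukocyte integrin Itgad by 2.9 ± 0.27, Mrc2, a collagen-uptake receptor, by 1.97 ± 0.11 and the acute-phase protein Saa3 by 1.76 ± 0.2. Of 20 macrophage markers 16 rose (19 adjusted over the list alone), with Itgax at 1.31 ± 0.16, Trem2 at 1.38 ± 0.21 and Gpnmb at 1.88 ± 0.25. Of 30 extracellular matrix genes 17 rose (adjusted over the list alone, 23 rose and 1 fell), with Col1a1 at 1.08 ± 0.12, and of 17 cytokine and acute-phase genes 9 rose (13 adjusted over the list alone), with the monocyte attractant Ccl2 at 1.38 ± 0.18. MHC class II genes (5 of 7 rose; 6 adjusted over the list alone) included H2-Ab1 at 1.11 ± 0.19. Cyp2e1 fell by 3.33 ± 0.19 (10.1-fold) and the glutathione transferase Gsta3 by 1.42 ± 0.13. Of 20 fatty acid synthesis genes 9 fell (10 adjusted over the list alone, and 1 rose), with Thrsp, a lipogenic co-factor, at -2.09 ± 0.23, Elovl6 at -1.45 ± 0.17, Acaca, acetyl-CoA carboxylase, at -1.13 ± 0.12 and Acly, ATP citrate lyase, at -1.08 ± 0.13. Of 36 oxidative phosphorylation genes 10 fell (17 adjusted over the list alone, and 1 rose). The 6 shifts of these lists passed in camera with adjusted p from 1.77e-14 to 1.17e-05 and had adjusted p = 0.114 to 0.286 with an estimated correlation. Of 10 skeletal muscle markers 4 fell (7 adjusted over the list alone; median -1.47), with the sarcoplasmic calcium pump Atp2a1 at -3.86 ± 0.56. Camera gave an adjusted p of 0.000231 and adjusted p = 0.387 with an estimated correlation. Over these 7 lists, with brightness as a covariate 13 macrophage, 12 matrix, 6 cytokine and acute-phase and 5 MHC class II genes rose. Those that fell numbered 8 for fatty acid synthesis, 4 for oxidative phosphorylation and 1 for skeletal muscle. Standard-diet replicate 1 had an Atp2a1 intensity of 14.13 against 9.73 to 10.68 on the other standard-diet arrays. Every gene named so far had all 6 high-fat arrays beyond all 6 standard-diet arrays (limma adjusted p from 1.5e-07 to 0.00153). Limma called 2189 of 17991 genes or unnamed probes, 50.3% of them higher (34.4% of 93 under median scaling). There were 1206 calls with brightness as a covariate, 155 with a term for the dim arrays (67.7% higher) and 59 over the bright arrays alone. The term for the dim arrays ended the calls of Trem2, Gpnmb, H2-Ab1 and Atp2a1, and those of Ucp1 and Lep. Without high-fat replicate 3 the count was 1325 and without replicate 6 it was 1420.

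In inguinal fat the largest rises were in Tph2 (4 ± 0.18, 16-fold), the haem-binding protein Hpx (3.38 ± 0.14, 10.4-fold), Ubd (2.98 ± 0.23), the iodotyrosine deiodinase Iyd (2.39 ± 0.13) and Saa3 (2.35 ± 0.21), and Hilpda, a lipid-droplet protein that inhibits lipolysis, rose by 2.01 ± 0.18. Of 18 cholesterol synthesis genes 9 rose (10 adjusted over the list alone), among them Nsdhl (0.98 ± 0.08), Lss (0.93 ± 0.08) and Insig1 (1.06 ± 0.1), although the list's median of 0.24 became -0.05 under median scaling, where the median of all genes was -0.271. This list passed in camera (adjusted p = 5.86e-07) and also with an estimated correlation (adjusted p = 0.0221). Of 22 fatty acid oxidation genes 11 rose and 2 fell (14 and 2 adjusted over the list alone; camera adjusted p = 1.27e-05, adjusted p = 0.141 with an estimated correlation), with Plin2, which coats lipid droplets, at 0.97 ± 0.1 and Etfdh at 0.76 ± 0.09. Of 20 fatty acid synthesis genes 4 rose and 7 fell (5 and 7 adjusted over the list alone; camera adjusted p = 0.583), and of 19 adipocyte lipid genes 2 rose and 3 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.785). Macrophage markers (15 of 20 rose; 16 adjusted over the list alone), with Itgax at 1.08 ± 0.14 and Mpeg1 at 1.27 ± 0.18, and cell cycle genes (13 of 20 rose; 17 adjusted over the list alone), with Cdk1 at 0.78 ± 0.1, shifted upward with camera adjusted p = 1.78e-08 and 5.09e-09 and adjusted p = 0.252 and 0.226 with an estimated correlation. Cyp2e1 fell by 2.63 ± 0.31, Gpx3, the plasma glutathione peroxidase, by 2.09 ± 0.21 and Thrsp by 1.78 ± 0.12. Xenobiotic metabolism genes (8 of 15 fell; 11 adjusted over the list alone) included Gsta3 at -1.39 ± 0.15. Their camera adjusted p was 1.27e-05, with adjusted p = 0.139 with an estimated correlation. With brightness as a covariate 6 cholesterol synthesis, 7 fatty acid oxidation, 8 macrophage and 10 cell cycle genes rose and 7 xenobiotic metabolism genes fell. The genes given had all 6 high-fat arrays beyond all 6 standard-diet arrays, and limma adjusted p from 1.98e-09 to 0.000186. Limma called 4248 of 17963 genes or unnamed probes, 46.5% of them higher (18% of 322 under median scaling). The count was 1990 with brightness as a covariate, 697 with a term for the dim arrays and 430 over the bright arrays alone (57% higher).

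In mesenteric fat Cyp2e1 fell by 2.92 ± 0.28, Elovl6, which elongates palmitate, by 2.19 ± 0.22 (4.57-fold), Thrsp by 1.9 ± 0.25, Acaca by 1.45 ± 0.16, Acly by 1.32 ± 0.14 and Acacb by 1.26 ± 0.15. Of 20 fatty acid synthesis genes 8 fell (12 adjusted over the list alone; 6 with brightness as a covariate). Camera gave an adjusted p of 2.43e-10, and adjusted p = 0.17 with an estimated correlation. Among genes that rose were Fabp3, a fatty acid carrier of muscle and brown fat (1.65 ± 0.15), and the clock output gene Dbp (1.43 ± 0.26). Of 12 circadian clock genes Dbp and Tef (0.83 ± 0.15) rose and Arntl, the activator of the clock loop, fell by 0.82 ± 0.16 (5 up and 1 down adjusted over the list alone). The list's median of 0.29 turned to -0.1 under median scaling, and its camera adjusted p of 8.33e-05 became adjusted p = 0.17 with an estimated correlation. The largest rises were in Reg2 (5.38 ± 0.86, 41.8-fold) and Reg3a (4.59 ± 0.75, 24-fold), secreted proteins of pancreas and gut. None of 13 markers of exocrine pancreas passed limma's test, either over all genes or adjusted over the list alone, with a list median of 1.71 (camera adjusted p = 0.00321; adjusted p = 0.767 with an estimated correlation and 0.406 with brightness as a covariate). The shift rested on standard-diet replicate 1, without which the list's mean went from 1.655 to 0.29 (camera adjusted p = 0.138). Cpb1, a pancreatic carboxypeptidase, had a mean log2 intensity of 13.49 (SD 3.36, n = 6) on the standard diet and 15.31 (SD 0.39, n = 6) on the high-fat diet. Its difference of 1.82 was 0.51 without that array, where its intensity was 6.83. On the other standard-diet arrays Cpb1 was at 13.21 to 15.34, so mesenteric samples of both diets held pancreatic transcripts. The rises of Reg2 and Reg3a were not tested apart from these. All 6 high-fat arrays lay beyond all 6 standard-diet arrays for each named gene except Cpb1, with limma adjusted p from 0.000581 to 0.0369 for those that passed. Limma called 118 of 18206 genes or unnamed probes, 46 higher and 72 lower (39% higher; 50% of 2 under median scaling). There were 1628 in the fit of all 96 arrays (33.4% higher), 267 with array weights and 15 with the replicate number as a block (20% higher). With brightness as a covariate 35 were called, and with a term for the dim arrays or over the bright arrays alone limma called 0, with 752 and 769 at an unadjusted p under 0.05. The calls of Reg3a, Dbp, Tef and Arntl ended with the covariate. Without 1 array the count was 52 (standard-diet replicate 2), 68 (3) or 61 (6), and 60 (high-fat replicate 3), 64 (5) or 66 (6). The calls of Dbp, Tef and Arntl ended without any 1 of 6, 5 and 9 arrays, standard-diet replicate 2 and high-fat replicate 3 among them (limma adjusted p up to 0.0788, 0.0783 and 0.11).

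In perirenal fat nearly all macrophage, MHC class II and cell cycle genes rose. Tph2 rose by 4.83 ± 0.18 (28.5-fold), Itgad by 4.37 ± 0.2 (20.6-fold), Lcn2 by 3.3 ± 0.17, Rgs1, a G protein regulator of immune cells, by 3.18 ± 0.24, Trem2, a lipid receptor of macrophages, by 2.92 ± 0.22 and Gpnmb by 2.86 ± 0.21. Of 21 macrophage markers 20 rose (20 adjusted over the list alone), all 7 MHC class II genes rose (7 adjusted over the list alone; H2-DMa at 1.46 ± 0.13), 18 of 20 cell cycle genes rose (19 adjusted over the list alone; Mcm5, a DNA replication helicase subunit, at 1.31 ± 0.14) and 17 of 29 extracellular matrix genes rose (19 adjusted over the list alone; Col1a1 at 1.02 ± 0.12). These 4 shifts had camera adjusted p from 3.64e-18 to 1.34e-07 and adjusted p = 0.196 with an estimated correlation. Thrsp fell by 2.91 ± 0.17 (7.53-fold), Cyp2e1 by 3.07 ± 0.26, Elovl6 by 2.38 ± 0.22 and Acly by 1.36 ± 0.12, and 11 of 20 fatty acid synthesis genes fell (11 adjusted over the list alone; camera adjusted p = 2.98e-06, adjusted p = 0.196 with an estimated correlation). Of 20 insulin and glucose genes 7 fell and 1 rose (7 and 2 adjusted over the list alone), with Slc2a4, the insulin-regulated glucose transporter, at -1.37 ± 0.13 and Irs1, which passes on the insulin receptor's signal, at -1.4 ± 0.16. Camera gave adjusted p = 0.033, and adjusted p = 0.348 with an estimated correlation. Oxidative phosphorylation genes (12 of 36 fell and 1 rose; 15 and 2 adjusted over the list alone) had Ndufa5 at -0.57 ± 0.09, and 4 of 7 mesothelium markers fell and 1 rose (4 and 1 adjusted over the list alone). Both lists had adjusted p = 0.348 with an estimated correlation. With brightness as a covariate the counts of the 4 lists that rose were the same, and 8 fatty acid synthesis, 6 insulin and glucose, 12 oxidative phosphorylation and 4 mesothelium genes fell. Each gene named showed all 6 high-fat arrays beyond all 6 standard-diet arrays (limma adjusted p from 5.13e-09 to 0.000393). Limma called 4760 of 17950 genes or unnamed probes, 2380 in each direction (50% higher; 64.1% of 1525 with a fold of at least 1.5). There were 3465 with brightness as a covariate, 1293 with a term for the dim arrays (67.7% higher), 855 over the bright arrays alone (72.5% higher) and 966 under median scaling (40.6% higher). The genes named here kept their calls with the covariate and with the term for the dim arrays.

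In subcutaneous fat several lipogenic genes fell and several acute-phase and matrix genes rose. Thrsp fell by 2.9 ± 0.14 (7.47-fold), Elovl6 by 2.69 ± 0.19 (6.46-fold), Cyp2e1 by 3.14 ± 0.3, Acacb by 1.97 ± 0.15 and Acly by 1.56 ± 0.11. Of 20 fatty acid synthesis genes 11 fell and 1 rose (12 and 2 adjusted over the list alone), and of 12 brown adipocyte genes 6 fell (6 adjusted over the list alone), including Cidea, a lipid-droplet protein abundant in brown fat (-1.5 ± 0.2), and Cox8b, a cytochrome oxidase subunit (-1.1 ± 0.15). Tph2 rose by 4.34 ± 0.21 (20.2-fold), S100a8, a calcium-binding protein of neutrophils, by 2.65 ± 0.21, Saa3 by 2.49 ± 0.28 and Ubd by 2.02 ± 0.15. Macrophage markers (11 of 20 rose; 12 adjusted over the list alone) included Mmp12 at 2.38 ± 0.32, and extracellular matrix genes (14 of 29 rose; 16 adjusted over the list alone) included Lox at 0.76 ± 0.09. Of 19 lymphocyte markers 11 fell (13 adjusted over the list alone; 3 with brightness as a covariate), with the T-cell receptor chain Cd3d at -1.01 ± 0.21 and 4 of 6 high-fat arrays below all 6 standard-diet arrays. Of 10 endothelial markers 5 rose (adjusted over the list alone, 8 rose and 1 fell), with Cdh5, the endothelial cadherin, at 1.02 ± 0.13. Of 8 skeletal muscle markers 2 rose (3 adjusted over the list alone), with Pvalb, a calcium buffer of fast muscle fibres, at 2.68 ± 0.17. In the other lists, with brightness as a covariate 10 fatty acid synthesis and 5 brown adipocyte genes fell, and 6 macrophage, 10 matrix, 5 endothelial and 2 skeletal muscle genes rose. The 7 list shifts had camera adjusted p from 1.03e-08 to 0.00349 and adjusted p = 0.311 with an estimated correlation. Apart from Cd3d (limma adjusted p = 0.00377), the genes named so far had all 6 high-fat arrays beyond all 6 standard-diet arrays, with limma adjusted p from 8.96e-09 to 0.000194. Limma called 3571 of 17990 genes or unnamed probes (1582 higher and 1989 lower, or 44.3% higher). It called 2084 with brightness as a covariate, 418 with a term for the dim arrays (65.6% higher), 117 over the bright arrays alone (65% higher) and 86 under median scaling. The term for the dim arrays ended the calls of Cd3d, Scd1 and Pdk4, which it left at -0.65, 0.19 and -0.74, from -1.01, 0.35 and -0.67 without it. Without high-fat replicate 3 the count was 2302 and without replicate 6 it was 2347.

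In liver Thrsp rose by 1.61 ± 0.16 (3.04-fold), Fads2, the rate-limiting fatty acid desaturase of polyunsaturated fat, by 1.42 ± 0.17, Fads1 by 0.6 ± 0.1 and the lipase Pnpla3 by 0.93 ± 0.15. Of 20 fatty acid synthesis genes 7 rose (10 adjusted over the list alone; camera adjusted p = 2.1e-12, adjusted p = 0.104 with an estimated correlation). Of 18 cholesterol synthesis genes Hsd17b7 (0.73 ± 0.09) and Fdps (0.48 ± 0.09) rose, and 9 did adjusted over the list alone (camera adjusted p = 2.8e-12, adjusted p = 0.191 with an estimated correlation). Mfsd2a, a transporter of lysophospholipids, rose by 1.86 ± 0.29 and the apolipoprotein Apoa4 by 1.18 ± 0.13. Cyp4a14, a fatty acid hydroxylase induced by the nuclear receptor PPARα, rose by 2.14 ± 0.43 (adjusted p = 0.0168 in limma, 5 of 6 high-fat arrays above all standard-diet arrays). Csad, an enzyme of taurine synthesis, fell by 1.78 ± 0.15 (3.43-fold), the glutathione transferase Gsta2 by 1.82 ± 0.22, Elovl3 by 1.34 ± 0.22, Lpl by 1.29 ± 0.18 and Ppp1r3c, a glycogen-targeting subunit of protein phosphatase, by 1.32 ± 0.17. Of 27 xenobiotic metabolism genes 6 fell and 1 rose (adjusted over the list alone, 9 fell and 4 rose; camera adjusted p = 0.0247, adjusted p = 0.549 with an estimated correlation). Of 11 clock genes Per2 (0.94 ± 0.17), Per3 (1.11 ± 0.26) and Tef (0.89 ± 0.18) rose and Nr1d1 (-0.66 ± 0.11) and Clock (-0.53 ± 0.1) fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.017, adjusted p = 0.549 with an estimated correlation). All 6 high-fat arrays lay beyond all 6 standard-diet arrays for the genes named, except Mfsd2a, Fdps and Cyp4a14 with 5, and limma adjusted p ran from 2.57e-05 to 0.0471. Limma called 207 of 18242 genes or unnamed probes, 111 higher and 96 lower. It called 137 on the authors' deposited values, where Cyp4a14, Per3 and Tef no longer passed, and 10 under median scaling. Per3 also did not pass with brightness as a covariate (limma adjusted p = 0.0673), and Apoa4 did not in the fit of all 96 arrays. Without high-fat replicate 5 the count was 129. The call of Cyp4a14 ended without high-fat replicate 1 (2.04, limma adjusted p = 0.0513), that of Tef without any 1 of 3 arrays (standard-diet replicate 1, high-fat replicates 1 and 5; adjusted p up to 0.0581 in limma) and that of Per3 without any 1 of 9 (up to 0.118).

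In muscle Lep, the adipocyte hormone leptin, rose by 1.92 ± 0.21 (3.79-fold), from a mean log2 intensity of 8.02 (SD 0.43, n = 6) to 9.94 (SD 0.47, n = 6), and Cyp2e1 fell by 1.79 ± 0.2. Mthfd2, a mitochondrial one-carbon enzyme, fell by 2.16 ± 0.17 (4.46-fold). Also lower were the pseudokinase Trib3 (-1.01 ± 0.17), the hormone Fgf21 (-1.05 ± 0.2), the amino acid transporter Slc7a5 (-0.89 ± 0.16) and the glycyl-tRNA synthetase Gars (-0.49 ± 0.07). The clock genes Per2 (0.8 ± 0.13), Dbp (0.83 ± 0.16) and Per3 (0.55 ± 0.1) rose among 13 measured, and 6 rose and 1 fell adjusted over the list alone. The list's median of 0.2 went to 0 under median scaling, and its camera adjusted p of 0.00285 became adjusted p = 0.0978 with an estimated correlation. Of 24 fatty acid oxidation genes 6 rose adjusted over the list alone and limma called 0 over all genes, where 1629 genes or unnamed probes had an unadjusted p under 0.05 (camera adjusted p = 0.00101, adjusted p = 0.196 with an estimated correlation). The list's median of 0.12 turned to -0.07 under median scaling. All 6 high-fat arrays lay beyond all 6 standard-diet arrays for these genes, except for Dbp, Per3 and Slc7a5 with 5, and limma adjusted p ran from 4.46e-06 to 0.0498. Limma called 35 of 18200 genes or unnamed probes, 48.6% of them higher. There were 18 on the authors' deposited values (66.7% higher), 14 without background correction, 11 with brightness as a covariate and 585 under median scaling (1.7% higher). In the fit of all 96 arrays 38.5% were higher, and Dbp, Per3, Fgf21 and Slc7a5 did not pass. Dbp, Per3 and Fgf21 did not pass on the authors' deposited values. The muscle arrays of both diets also split by number, with 1041 genes or unnamed probes called between replicates 1 to 3 and 4 to 6. With that division as a batch term the diet count was 86, and within each part it was 21 and 6. Leaving out 1 array gave 13 (high-fat replicate 4), 15 (6), 17 (5), 18 (3), 18 (2), 18 (standard-diet replicate 5), 20 (1), 20 (2) or 22 (3). The call of Per2 ended without high-fat replicate 4 (0.78, limma adjusted p = 0.0701), and the calls of Dbp, Fgf21, Slc7a5, Per3 and Trib3 ended without any 1 of 11, 9, 8, 7 and 4 arrays, high-fat replicate 4 among them (limma adjusted p up to 0.115). These 6 also did not pass with brightness as a covariate.

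Among 6 genes fixed for every tissue, Mest, an imprinted gene that marks fat-pad expansion, rose in all 6 fat tissues, by 2.16 ± 0.14 in brown, 2.09 ± 0.26 in subcutaneous, 1.81 ± 0.23 in mesenteric, 1.22 ± 0.17 in inguinal, 1 ± 0.13 in gonadal and 0.78 ± 0.21 in perirenal fat (limma adjusted p at most 0.0162; all 6 high-fat arrays above all standard-diet arrays, except 5 in perirenal fat). Its call in mesenteric fat ended with a term for the dim arrays (1.99, limma adjusted p = 0.108). Lep rose in brown (1.92 ± 0.26), mesenteric (1.49 ± 0.25), subcutaneous (0.91 ± 0.11), gonadal (0.48 ± 0.1) and perirenal fat (0.46 ± 0.14). The term for the dim arrays ended its calls in gonadal (0.32, limma adjusted p = 0.297), mesenteric (1.23, 0.835) and perirenal fat (0.22, 0.538). The fit of all 96 arrays ended those in gonadal and perirenal fat, and brightness as a covariate that in perirenal fat. In inguinal fat the difference was 0 ± 0.14. Ucp1, the uncoupling protein of brown adipocytes, rose in 4 white depots, by 2.35 ± 0.42 in gonadal, 2.22 ± 0.36 in inguinal, 2.09 ± 0.21 in mesenteric and 1.16 ± 0.28 in perirenal fat (limma adjusted p at most 0.00883; 6, 5, 6 and 5 high-fat arrays above all standard-diet arrays). In brown fat it differed by 0.33 ± 0.12 (adjusted p = 0.0719 in limma) and in subcutaneous fat by 0.16 ± 0.12 (adjusted p = 0.367 in limma). Its standard-diet means there were 15.07 and 14.63, near the top of the scale, which leaves little room to read a rise. With a term for the dim arrays the calls of Ucp1 ended in the 4 depots, at 1.43 ± 0.5, 1.66 ± 0.49, 1.95 ± 0.3 and 0.37 ± 0.27. Fasn, fatty acid synthase, passed in no tissue, with differences from -1 ± 0.32 in muscle to 0.19 ± 0.18 in brown fat. With brightness as a covariate it passed in perirenal (-0.72) and subcutaneous fat (-0.49). Scd1, the stearoyl-CoA desaturase, rose in brown (0.36 ± 0.12) and subcutaneous fat (0.35 ± 0.1), and Pdk4, which blocks pyruvate oxidation, fell in brown (-0.33 ± 0.11) and subcutaneous fat (-0.67 ± 0.14). Of these 4 calls only that of Pdk4 in subcutaneous fat held with brightness as a covariate, and none held with a term for the dim arrays, where Pdk4 in subcutaneous fat was at -0.74 (limma adjusted p = 0.073). The calls of Scd1 and Pdk4 in brown fat ended without any 1 of 10 and 9 arrays, that of Scd1 in subcutaneous fat without any 1 of high-fat replicates 3 to 6, and that of Lep in perirenal fat without any 1 of 8 arrays (limma adjusted p up to 0.117, 0.11, 0.0759 and 0.07).

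**Figure D2:**
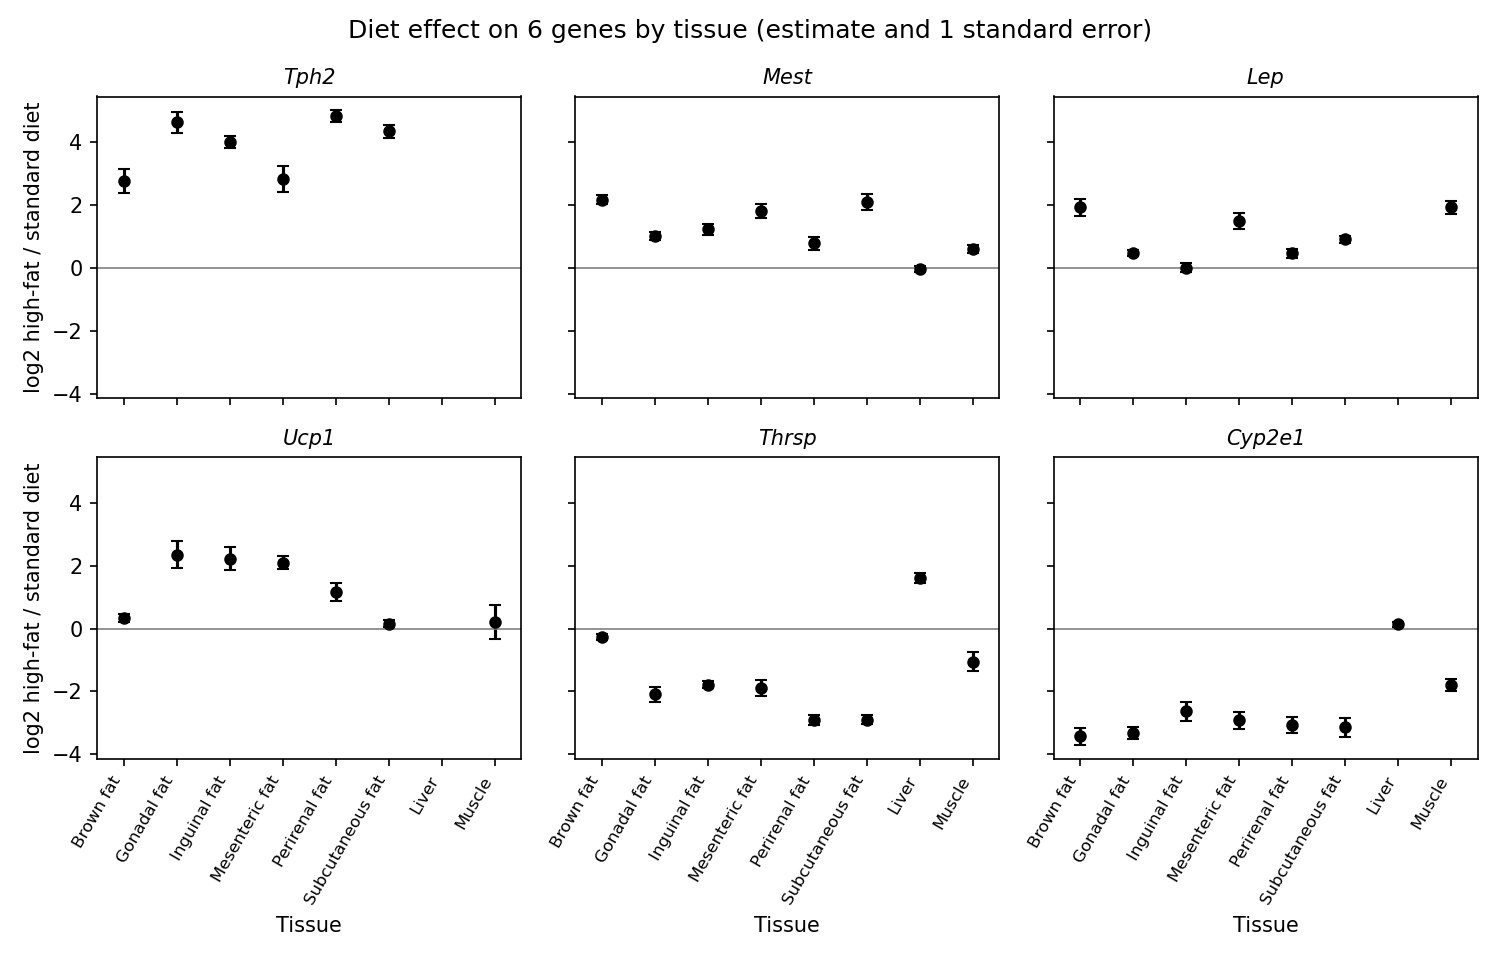
Log2 difference between high-fat and standard diet of Tph2, Mest, Lep, Ucp1, Thrsp and Cyp2e1 in each tissue where the gene was tested; points are limma estimates, bars are 1 standard error, and n = 6 arrays per diet. Thrsp is at -2.91 in perirenal fat and 1.61 in liver, and Cyp2e1 lies between -3.43 and -1.79 in the 6 fat tissues and muscle.

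Across the 6 fat tissues 17 genes rose in all and 22 fell in all (2 and 6 with brightness as a covariate, 0 and 0 with a term for the dim arrays). Those that fell included Hsd11b1, which regenerates glucocorticoid inside cells (-0.65 in brown to -1.34 in subcutaneous fat), Irs1 (-0.6 to -1.4), Acacb (-0.63 to -1.97), Elovl6 (-0.57 to -2.69) and Cyp2e1 (-2.63 to -3.43). Those that rose included Tph2 (2.76 to 4.83), Ubd (0.88 to 3.3), Mrc2 (0.56 to 1.97) and Cxcl1 (0.58 to 1.22). Leaving mesenteric fat out, 182 genes rose and 166 fell in all 5 others (65 and 58 with the covariate; 12 and 2 with the term). Perirenal and inguinal fat shared 995 genes that rose in both and 1103 that fell in both, where independent lists of these lengths would share 261 and 301. The tissues have no arrays in common. Arrays of different fat tissues with the same diet and number deviated together, so these overlaps are not between independent samples.

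The diet effect itself differed between tissues for many genes. Over all 8 tissues 5401 of 22254 genes or unnamed probes passed the limma test for a difference in effect, the smallest p including Thrsp, which fell by 2.91 in perirenal fat and rose by 1.61 in liver, and Acacb, at -1.97 in subcutaneous fat and 0.74 in liver. Itgad ranged from -0.04 in muscle to 4.37 in perirenal fat, Gstt1, a glutathione transferase, from -1.41 in inguinal to 0.19 in brown fat, and Il7r, the interleukin-7 receptor, from -0.1 in muscle to 2.77 in perirenal fat. Among the 5 white depots 1912 of 19819 passed. Of the 10 genes with the smallest p, Fam122b had the smallest (0.01 in mesenteric to 1.55 in inguinal fat). Reg2 had the widest range, from 0.03 in gonadal to 5.38 in mesenteric fat, whose samples held pancreatic transcripts. Others were Il7r (-0.03 in mesenteric to 2.77 in perirenal fat), Itgad (0.19 to 4.37 in the same depots), Pik3ap1, a signalling adaptor of B cells and macrophages (-0.39 to 1.31), and the B-cell receptor partner Cd72 (-0.59 in subcutaneous to 2.16 in perirenal fat). Between intra-abdominal and subcutaneous white fat 274 passed, 155 with a higher and 119 with a lower effect inside the abdomen. Il1r2, the decoy receptor of interleukin-1, had an effect 1.31 ± 0.19 higher in intra-abdominal depots (n = 60 arrays), with -1.58 in inguinal and 0.16 in perirenal fat, whereas the growth factor Fgf9 (-0.74 ± 0.1) and the adipokine resistin, Retn (-0.68 ± 0.12), had lower effects there. The 3 counts were 3324, 1139 and 80 with brightness as a covariate, and 1712, 251 and 0 with a term for the dim arrays, where the last count of limma was 760 at an unadjusted p under 0.05. The fits so far treat the arrays as independent, although same-numbered fat arrays deviated together, and with the same diet and number as a random block the counts were 7979, 4216 and 1012. Under median scaling they were 1006, 207 and 14, the last with 6 higher and 8 lower. Without perirenal fat the depot count was 827 and without inguinal fat 1241, and the intra-abdominal count was 93 without perirenal, 158 without gonadal and 987 without mesenteric fat.

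Averaged over the 8 tissues with equal weight, 12961 of 22254 genes or unnamed probes passed, 6099 higher and 6862 lower. The standard errors here treat the 96 arrays as independent. Same-numbered arrays of different fat tissues deviated together (mean correlation 0.38 across genes, which are not independent replicates), and with the same diet and number as a random block the count was 7604, 3575 higher and 4029 lower. Tph2 had the largest mean rise among the 10 genes with the smallest p (2.97 ± 0.11, n = 96 arrays), followed by Ubd (2.01 ± 0.1) and Itgad (1.6 ± 0.09), and Cyp2e1 the largest mean fall (-2.52 ± 0.1). In liver Tph2 differed by -0.1 and Cyp2e1 by 0.13, so the mean does not describe that tissue. Hsd11b1 fell by 0.81 ± 0.04 on average and Snhg11, a noncoding RNA gene, by 1.01 ± 0.05. With a term for the dim arrays the count was 5753, and under median scaling it was 14903 with 2655 higher and 12248 lower. Under that scaling the median of all genes was itself shifted, by -0.233 in brown, -0.263 in gonadal, -0.271 in inguinal, -0.287 in mesenteric, -0.181 in perirenal and -0.212 in subcutaneous fat, -0.02 in liver and -0.089 in muscle, so lower genes there are partly lower relative to an array median that had moved.

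On the standard diet, positional genes set the depots apart. Upk3b, a marker of the mesothelial lining of the abdominal cavity, was 5.4 ± 0.13 higher in intra-abdominal than in subcutaneous depots on the log2 scale, and Wt1, a transcription factor of visceral fat progenitors, 3.02 ± 0.1 higher (n = 6 arrays per depot). Hoxa5 was 0.74 ± 0.08 higher and Thbd 0.35 ± 0.13 higher (adjusted p = 0.0392 in limma). The limb and trunk patterning genes Shox2 (-3.77 ± 0.12), En1 (-1.41 ± 0.08), Hoxc9 (-1.18 ± 0.1), Sfrp2 (-0.9 ± 0.15), Hoxc10 (-0.73 ± 0.06) and Hoxa10 (-0.46 ± 0.06) were lower on average in intra-abdominal depots. Several of these differences have a size that depends on the background offset, because the lower means lay near or below the median of all probes on these arrays (7.01; lowest value 5.68). These means were 6.43 and 6.33 for Upk3b and 7.03 and 7.01 for Wt1 in inguinal and subcutaneous fat. In mesenteric fat they were 6.61 for Shox2, 6.95 for En1 and 6.79 for Sfrp2, in gonadal fat 7.08 for Hoxc10 and 6.58 for Hoxa10. The depots did not fall into 2 blocks for every gene: Hoxc9 had a mean log2 intensity of 8.65 (SD 0.47) in mesenteric and 11.42 (SD 0.24) in perirenal fat, against 11.29 (SD 0.2) in inguinal fat, and En1 was at 8.85 (SD 0.19) in perirenal and 6.95 (SD 0.12) in mesenteric fat. Sfrp2 was at 7.78 in gonadal and 7.62 in perirenal fat, against 7.7 in subcutaneous fat. In perirenal fat Hoxc10 (8.23) and Hoxa10 (7.26) were close to their means in subcutaneous fat (8.15 and 7.27). Tbx15, Nr2f1, Hoxc8 and Gpc4 did not pass, with differences of -0.17 ± 0.08, 0.15 ± 0.07, -0.02 ± 0.1 and -0.01 ± 0.1. Limma called 4059 of 18050 genes or unnamed probes between the 2 kinds of depot, 1528 higher and 2531 lower inside the abdomen, and 1505 under median scaling. Of the 10 ways to divide the 5 depots 3 against 2, 8 gave at least as many calls, up to 8743, so the count does not single out this division.

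**Figure D3:**
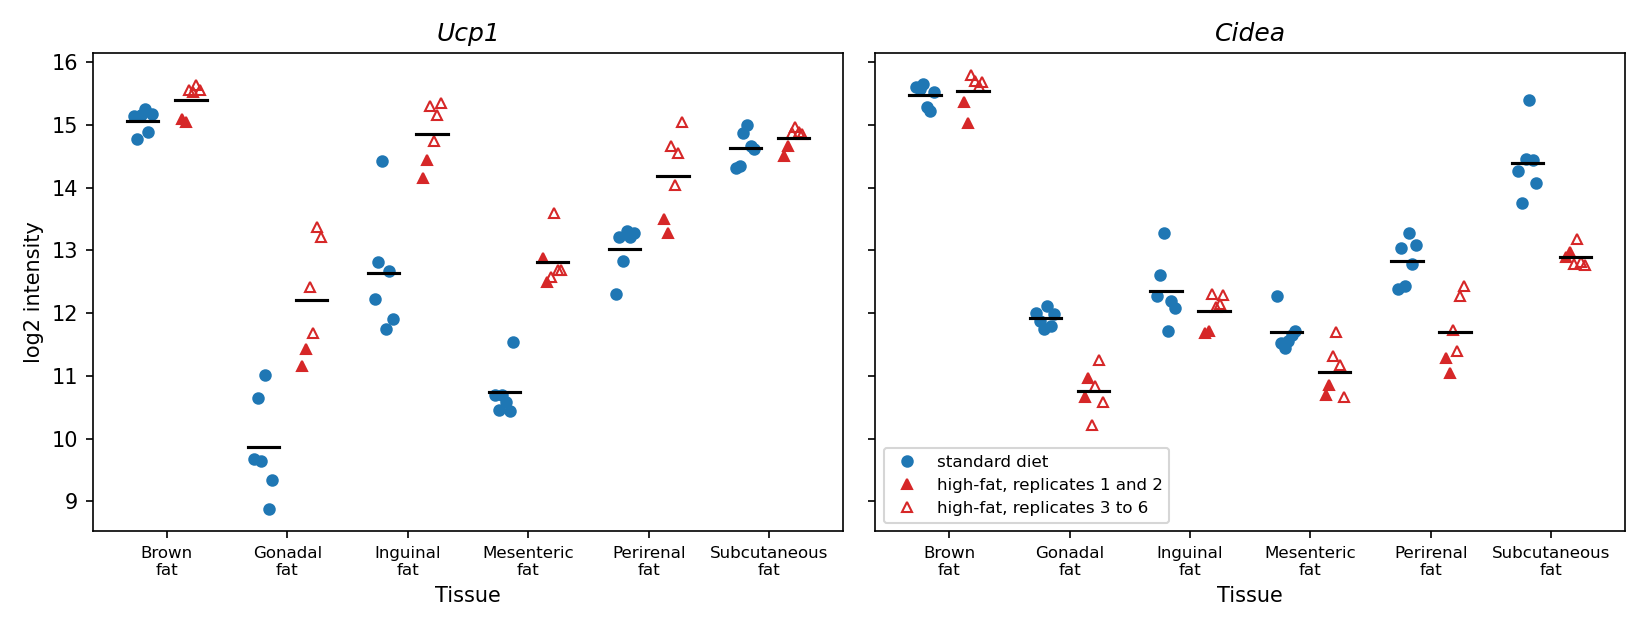
Log2 intensity of Ucp1 and of Cidea, which is also abundant in brown fat, on each array of the 6 fat tissues; circles are standard-diet arrays, filled triangles high-fat replicates 1 and 2, open triangles high-fat replicates 3 to 6, and bars are means of 6. Ucp1 has a standard-diet mean of 9.86 in gonadal fat and 15.07 in brown fat, and in gonadal fat Cidea differs by -1.16 while Ucp1 differs by 2.35.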

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

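The tests of explanations, the counts over other splits of the samples, and the fits with brightness or the dim arrays were chosen only after the results had been seen, while the tests of differences between tissues were planned.

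The diet effect differed between groups of tissues in 3 planned tests, with 5401 genes or unnamed probes between the 8 tissues, 1912 between the 5 white depots and 274 between intra-abdominal and subcutaneous white fat. Between the 8 tissues the range of log2 differences, highest minus lowest, was 4.93 for Tph2, 4.52 for Thrsp, 4.41 for Itgad, 2.86 for Il7r, 2.72 for Acacb, 2.25 for Itgax, 1.85 for Eci3, 1.63 for Fam122b, 1.6 for Gstt1 and 1.57 for Slc43a1. Between the white depots it was 5.35 for Reg2, 4.18 for Itgad, 2.79 for Il7r, 2.75 for Cd72, 2.09 for Cytip, 1.87 for Myo1e, 1.7 for Pik3ap1, 1.54 for Fam122b, 1.51 for Dock2 and 1.47 for Gstt1. The effect in intra-abdominal minus that in subcutaneous depots was 1.31 for Il1r2, 0.86 for Il1rl2, 0.64 for Tnfrsf13b, 0.54 for Cdsn and 0.51 for Cnn2, and it was -0.96 for Dnajc6, -0.74 for Fgf9, -0.68 for Retn, -0.57 for Fam122b and -0.43 for Pex3. These are the 10 genes with the smallest p of each test. All 30 passed with brightness as a covariate, but for the intra-abdominal contrast 0 genes passed with a term for the dim arrays (760 in limma at an unadjusted p under 0.05).

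A single array lay far from the other 5 of its group for 21 of 342 groups of values of the genes named (6.1%), 12 of them on the standard diet and 9 on the high-fat diet. Chance alone marks about 1 in 20 groups. In brown fat these were Lcn2 on high-fat replicate 1 (8.65 against 9.6 to 9.86 on the others, log2 intensity) and Tjp3 on standard-diet replicate 4 (8.89 against 8.3 to 8.52). In gonadal fat they were Atp2a1 on standard-diet replicate 1 (14.13 against 9.73 to 10.68), Gsta3 on high-fat replicate 4 (12.25, with the group's other end at 11.55) and Lep on high-fat replicate 1 (15.26 against 15.56 to 15.7). In inguinal fat it was Tph2 on standard-diet replicate 2 (8.87 against 8.34 to 8.47). In mesenteric fat Ucp1 stood out on standard-diet replicate 6 (11.54 against 10.44 to 10.7) and on high-fat replicate 4 (13.59 against 12.49 to 12.88), Acacb on high-fat replicate 3 (10.74 against 11.17 to 11.37) and Cpb1 on standard-diet replicate 1 (6.83 against 13.21 to 15.34). In perirenal fat they were Itgad on standard-diet replicate 5 (7.99 against 6.78 to 7.22), Mest on standard-diet replicate 4 (12.4 against 13.28 to 13.69) and Gpnmb on high-fat replicate 5 (11.88 against 11.29 to 11.43). In subcutaneous fat they were Saa3 (10.86 against 8.73 to 9.49) and Scd1 (14.83 against 15.18 to 15.38) on standard-diet replicate 2 and Fasn on high-fat replicate 2 (12.94 against 13.95 to 14.5). In liver standard-diet replicate 2 was low for Gsta2 (12.05 against 13.04 to 13.6) and Per2 (7.94 against 8.73 to 9.17), standard-diet replicate 6 for Fads1 (13.24 against 13.76 to 13.93) and high-fat replicate 6 for Lpl (8.12 against 8.88 to 9.18). In muscle Lep on high-fat replicate 5 was 10.85 against 9.61 to 10.

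Whether a grouping of the arrays by chance would give as many calls was counted over 100 splits, the real one included. Only 1 of 100 splits, the real one, gave as many genes in brown fat (2712; highest other 2), gonadal fat (2189; highest other 0), inguinal fat (4248; highest other 617), mesenteric fat (118; highest other 1), perirenal fat (4760; highest other 800), subcutaneous fat (3571; highest other 522) and liver (207; highest other 3), which excludes a grouping by chance there. The same held for the differences between the 8 tissues (1 of 100; 5401 against 1781), between the 5 depots (1 of 100; 1912 against 375), for the intra-abdominal contrast (1 of 100; 274 against 58) and for the mean effect (1 of 100; 12961 against 11275, with a median of 640 over the other splits, so this test called many genes under ordinary splits too), where the highest other split, in each, had all 4 dim arrays on one side. These splits do not separate the diet from the dim arrays. In muscle 3 of 100 splits gave at least the 35 genes of the diet, a share under 0.05, with 1041 and 80 genes in the others. The highest, with 1041, put replicates 1 to 3 of both diets against 4 to 6, which points to a structure of these arrays, and with that division as a term the diet count was 86. Among 100 of the 200 splits that part each of these number groups 3 against 3, with the same term, only the real one gave as many (86; highest other 3). For the lists, 2 of 100 splits gave at least 84 shifts, the real one and another with 88. Splits other than the real one had a median of 49, so camera with the preset correlation passed many lists under any split. The count of shifts therefore does not exclude a grouping by chance for the lists named. For the depots on the standard diet the 10 splits are too few for a share under 0.05: 8 of the 10 gave as many as the real 4059, the highest 8743.

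The 17480 calls in 5 fat tissues (all but mesenteric fat) coincide with the dim high-fat arrays. High-fat replicates 3 to 6 and the bright replicates 1 and 2 were each set against 3 different standard-diet arrays, and of the genes called in both comparisons 726 had the same direction and 1 the opposite, which is 99.9% and argues against the dim arrays as the cause for these genes. For the 21724 calls made with replicates 3 to 6 and not with replicates 1 and 2, 64.7% had the same sign in both (56.4% in brown to 74.9% in perirenal fat, against 53.9% and 64.9% of all genes there), short of a shared direction, so for these the dim arrays and the diet cannot be told apart. With brightness as a covariate 9396 of the 17480 calls kept their direction and their call and 8084 did not, while the median share of the fold kept in the 5 tissues was 0.82 to 0.92 and the standard error rose 1.02-fold to 1.08-fold, so whether those 8084 rest on the diet stays open. The diet itself was not tested apart from the arrays, since no array batch is labelled.

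Ucp1 was higher in 4 white depots on the high-fat diet, and brown fat tissue carried into the high-fat samples as the whole cause would bring other transcripts of brown fat with it. With the fat arrays normalized together, brown fat would need to make up 9.2% of the RNA in gonadal, 26.3% in mesenteric and 35% in perirenal fat, which would move 11 other brown fat genes by medians of 1.02, 1.94 and 1.81; they moved by -0.13, 0.02 and -0.11, a median shortfall of at least 1.15 (SD over genes 0.78), which argues against it there (at least 0.75, SD 0.55, without the 4 genes above 14 in brown fat). These shares take the level of Ucp1 in brown fat (15.09, near the top of the scale) as linear: were it 2 times as high as read the shortfall would be at least 0.73 (SD 0.67), and were it 4 times as high it would be 0.41 (SD 0.61) in gonadal fat and 0.77 (SD 0.48) and 0.93 (SD 0.51) in the others, so for gonadal fat the argument needs a compression well under 4-fold. In inguinal fat the share needed was 75.4% and the shortfall 2.83 (SD 1.09), and still 1.01 (SD 0.81) with Ucp1 4 times as high, which argues against it as the whole cause there too, although 4 of the 11 genes rose (Elovl3 1.38, Cox7a1 0.85, Otop1 0.78 and Kcnk3 0.61) and a smaller carried-over part stays open. In subcutaneous fat, where Ucp1 differed by 0.16, Cidea fell by 1.5 and Cox8b by 1.1, both among the 4 genes above 14. The readings for the 4 depots take the 11 genes as not themselves lowered by the diet. Of the 11 genes, however, 2 were called lower in gonadal fat (1 higher) and 2 in perirenal fat (0 higher). Cidea differed by -1.16 and -1.14 in these depots, and Cox8b by -1.07 and -1.04. Carried-over brown fat would not lower these genes, so the readings are weaker in gonadal and perirenal fat. In inguinal and mesenteric fat 0 of the 11 were called lower. Why the genes were lower was not tested, and the readings would be weaker still if the diet lowered others of the 11. The dim arrays as the whole cause are argued against in gonadal, inguinal and mesenteric fat, where the term for them left 1.43 ± 0.5, 1.66 ± 0.49 and 1.95 ± 0.3, from 2.35 ± 0.42, 2.22 ± 0.36 and 2.09 ± 0.21 without it; in perirenal fat it left 0.37 ± 0.27 from 1.16 ± 0.28, and there the dim arrays and the diet cannot be told apart, while in gonadal, inguinal and mesenteric fat a response of Ucp1 to the diet that most of these genes do not share may remain as an explanation, not tested apart from the diet groups.

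Lep was higher and Cyp2e1 lower in muscle on the high-fat diet, as in most fat tissues. More adipocytes in the high-fat muscle samples would raise adipocyte genes together by about as much as Lep (1.92). But 13 of them had a median difference of 0.03 (SD 0.17), the highest 0.45 for Cidec, which argues against more adipocytes. Plin1 (-0.04) and Fabp4 (-0.01) were near background in standard-diet muscle (6.89 and 6.87), where a change is hard to read. Brighter genes also stayed well below Lep: Adipoq at 0.33 (mean 10.17), Mgll at 0.21 (11.1) and Plin4 at 0.02 (12.32). The reading takes these genes as not themselves lowered by the diet within adipocytes, which was not tested. In perirenal fat Lipe differed by -0.82 and Plin1 by -0.62. A similar amount of adipocyte RNA in the muscle samples of both diets, carrying the response of fat, may explain part of the pattern. The 173 genes called in at least 5 fat tissues and at least 4 times as bright in white fat as in muscle moved in the fat tissues' direction by a mean of 0.108 (one-sided exact permutation p = 0.0011, the smallest that 924 relabellings can give). The other 167 such genes moved by 0.013 (exact permutation p = 0.24), and in liver the bright genes moved by -0.021 (exact permutation p = 0.76). The 173 genes include Lep and Cyp2e1 themselves, so their mean is not independent of the pattern. It was not taken without them. Lep also rose by more in muscle than in mesenteric (1.49), subcutaneous (0.91) or perirenal fat (0.46). Taken as read, a similar amount of RNA from these depots would not by itself bring so large a rise. In perirenal and subcutaneous fat, however, Lep stood at 15 and 14.66 on the standard diet, near the top of the scale. Its rises there may be read too small, so they do not bound what adipocyte RNA could bring. In mesenteric fat it went from 12.51 to 14.01, below that range. In brown fat Lep rose as much as in muscle. A response of muscle cells themselves to the diet stays open and was not tested.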

How the results depend on the processing

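Array brightness as a covariate, the term for the dim arrays, the bright arrays alone and the number groups of muscle were chosen only after the results had been seen; the other alternatives were planned. Among the genes named and the lists, by camera's direction relative to all genes, none reversed its direction while called. Over all genes called, median scaling turned the sign of 249 in brown, 232 in gonadal, 591 in inguinal, 35 in perirenal and 137 in subcutaneous fat. The term for the dim arrays turned 19, 4, 63, 9 and 20 in the same order, and the bright arrays alone turned 16, 4, 56, 9 and 17. Counts that moved by more than 1.5 times are given by setting, and unless stated the cause was not tested.

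Median scaling gave 99 calls in brown, 93 in gonadal, 322 in inguinal, 2 in mesenteric, 966 in perirenal and 86 in subcutaneous fat, 10 in liver and 585 in muscle. For the joint tests it gave 1006 between the 8 tissues, 207 between the 5 depots and 14 for the intra-abdominal contrast, and it gave 1505 between depots on the standard diet. On the authors' deposited values there were 197 calls in mesenteric fat, 137 in liver and 18 in muscle, and without background correction 183 in mesenteric fat and 14 in muscle. All 96 arrays in 1 fit gave 3494 in gonadal and 1628 in mesenteric fat. Array weights gave 5112 in brown, 3354 in gonadal, 267 in mesenteric and 5569 in subcutaneous fat and 83 in muscle. A fold of at least 1.5 added a criterion, so the counts could only fall: 521 in brown, 673 in gonadal, 991 in inguinal, 1525 in perirenal and 823 in subcutaneous fat, 78 in liver and 18 in muscle.

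Brightness as a covariate gave 1176 in brown, 1206 in gonadal, 1990 in inguinal, 35 in mesenteric and 2084 in subcutaneous fat, 11 in muscle, and 3324, 1139 and 80 in the tests between tissues, between depots and for the intra-abdominal contrast. The term for the dim arrays gave 178 in brown, 155 in gonadal, 697 in inguinal, 0 in mesenteric (752 in limma at an unadjusted p under 0.05), 1293 in perirenal and 418 in subcutaneous fat, and 1712, 251 and 0 (760 in limma at an unadjusted p under 0.05) in those tests and 5753 for the mean effect. This term leaves 2 high-fat arrays to carry the diet effect: the standard error rose 1.29-fold in brown to 1.41-fold in mesenteric fat, and the median share of a called gene's fold that was left ran from 0.66 in brown to 0.89 in mesenteric fat, so both account for the loss. The bright arrays alone, which are fewer, gave 70, 59, 430, 0 (769 in limma at an unadjusted p under 0.05), 855 and 117 in brown, gonadal, inguinal, mesenteric, perirenal and subcutaneous fat. With the number groups as a term muscle had 86.

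The replicate number as a block gave 3095 calls in brown, 2545 in gonadal, 4257 in inguinal, 15 in mesenteric, 4937 in perirenal and 3833 in subcutaneous fat, 295 in liver and 66 in muscle. The numbers were not taken to pair the samples, since not all 6 pairs correlated above 0.1 in any tissue: 3, 3, 3, 2, 4 and 4 in these fat tissues, 4 in liver and 3 in muscle correlated above 0.1, and 2, 2, 2, 1, 3, 3, 4 and 2 of the 6 had their own number as the best match. A shared structure by number stays open where several pairs correlated, as in liver, perirenal and subcutaneous fat, and in muscle with its number groups. The same diet and number across tissues as a random block gave 4216 between the 5 depots, 1012 for the intra-abdominal contrast and 7604 for the mean effect, with a correlation of 0.318 over the 60 white fat arrays and 0.19 over all 96.

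Leaving out 1 array at a time gave 1530 to 4124 calls in brown, 1325 to 3000 in gonadal, 3079 to 5383 in inguinal, 52 to 153 in mesenteric, 3587 to 5391 in perirenal and 2302 to 4435 in subcutaneous fat, 129 to 239 in liver and 13 to 33 in muscle. Without inguinal fat the test between depots gave 1241 and without perirenal fat 827. The intra-abdominal contrast gave 158 without gonadal, 987 without mesenteric and 93 without perirenal fat.

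Of the 84 list shifts 1 passed with an estimated correlation, that of cholesterol synthesis in inguinal fat. Of 144 called single genes, 64 lost their call in the same direction under median scaling, 15 with brightness as a covariate, 10 in the fit of all arrays, 6 on the authors' values, 6 without background correction, 6 with the replicate block, 2 without the filter and 0 with array weights; 16 ever did when an array was left out. In the fat tissues 29 of 115 did with the term for the dim arrays and 47 of 114 with the bright arrays alone. Of 84 lists, 17 ever did when an array was left out, 11 under median scaling and 6 with brightness, and of the 67 in fat tissues 7 did with the term for the dim arrays and 9 with the bright arrays alone.

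The chip as a block and the filter on probes detected on all 12 arrays of a tissue, and in all tissues compared, could not be run, because no chip is labelled and the tables used here hold no detection values. Signal over background limits the weak transcripts: probes below the tissue's median were not tested, and on the dim arrays of brown fat the upper quartile of signal was 1.34 to 1.45 times the median. In liver it was 1.25 to 1.36 times and in muscle 1.3 to 1.39 times the median on the arrays of both diets.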

Other observations

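Both comparisons here, of array numbers across tissues and of high-fat arrays with each other, were chosen only after the results had been seen, while the lists at the end were planned.

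Arrays of 2 different fat tissues with the same diet and number deviated from their group means together, with a mean correlation across genes of 0.38 over 15 pairs of tissues (lowest 0.23, highest 0.52), against -0.08 for other numbers. For a fat tissue and liver or muscle the mean was 0.03, and for liver and muscle 0.01. Genes are not independent replicates. Within the high-fat group, replicates 3 to 6 against 1 and 2 gave 1963 calls in brown, 2029 in gonadal, 1849 in inguinal, 412 in perirenal and 1445 in subcutaneous fat. In mesenteric fat, liver and muscle limma called 0, with 2271, 1468 and 1371 at an unadjusted p under 0.05.

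Further lists of genes shifted in limma's camera test with the preset correlation, each with an adjusted p of at least 0.106 with an estimated correlation. The counts are those without brightness as a covariate. In brown fat adipokines and fat-pad expansion genes rose (8 of 16; 8 adjusted over the list alone) and so did cell cycle genes (7 of 17; 10 adjusted over the list alone), while endothelial markers (3 of 10 rose; adjusted over the list alone, 7 rose and 2 fell) had a median that turned to -0.11 under median scaling. In gonadal fat cell cycle genes rose (7 of 20; 11 adjusted over the list alone), and xenobiotic metabolism genes (4 of 15; 4 adjusted over the list alone) and mesothelium markers (3 of 7; 5 adjusted over the list alone) fell. Immediate early and lymphocyte genes there (3 of 11 and 3 of 12 rose; 4 and 4 adjusted over the list alone) had medians that turned to -0.29 and -0.03 under median scaling. In inguinal fat cytokines and acute-phase genes (10 of 17 rose and 1 fell, the same adjusted over the list alone) and exocrine pancreas markers (2 of 8; 2 adjusted over the list alone) moved up and smooth muscle markers down (5 of 7; 5 adjusted over the list alone). MHC class II genes and lymphocyte markers there (3 of 7 and 3 of 12 rose; 5 and 3 adjusted over the list alone) turned to medians of -0.05 and -0.03 under median scaling. In mesenteric fat 3 of 16 adipokines and fat-pad expansion genes rose (adjusted over the list alone, 7 rose and 1 fell) and 2 of 18 cytokines and acute-phase genes (6 adjusted over the list alone). Macrophage markers there (1 of 20; 4 adjusted over the list alone) and extracellular matrix genes (0 of 29 in limma, where 5 rose adjusted over the list alone) turned to -0.11 and -0.16 under median scaling.

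In perirenal fat cytokines and acute-phase genes (12 of 19 rose and 1 fell; 12 and 2 adjusted over the list alone), glutathione genes (7 of 14 rose and 2 fell, the same adjusted over the list alone) and lymphocyte markers (6 of 13 rose and 1 fell, the same adjusted over the list alone) moved up. Adipocyte lipid genes (6 of 19), xenobiotic metabolism genes (6 of 22) and smooth muscle markers (4 of 7) fell, with the same counts adjusted over the list alone. Immediate early genes rose (4 of 11; adjusted over the list alone, 5 rose and 1 fell), with a median of -0.03 under median scaling. In subcutaneous fat oxidative phosphorylation genes fell (10 of 36; adjusted over the list alone, 11 fell and 1 rose). Adipokines and fat-pad expansion genes (5 of 16 rose and 1 fell; 10 and 1 adjusted over the list alone), cytokines and acute-phase genes (6 of 18 rose and 1 fell; 7 and 1 adjusted over the list alone), hepatocyte markers (2 of 8; 2 adjusted over the list alone) and exocrine pancreas markers (1 of 10; 1 adjusted over the list alone) moved up. Cell cycle and immediate early genes there (5 of 20 and 3 of 11 rose; 5 and 4 adjusted over the list alone) turned to medians of -0.03 and -0.02 under median scaling.

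In liver fatty acid oxidation genes (1 of 23; 3 adjusted over the list alone) and interferon genes (2 of 15; 3 adjusted over the list alone) shifted upward, and endoplasmic reticulum stress genes downward (median -0.171) with 0 of 15 called by limma either way. In muscle 8 lists shifted with few or no calls: cholesterol synthesis (median -0.046; 1 fell adjusted over the list alone), fatty acid synthesis (-0.133; adjusted over the list alone, 7 fell and 3 rose), extracellular matrix (-0.066), endoplasmic reticulum stress (-0.105; 1 fell adjusted over the list alone) and smooth muscle markers (-0.162; 1 of 7 fell, 2 adjusted over the list alone) went down. Adipokines and fat-pad expansion genes (0.087; 1 of 17 rose and 2 fell, 7 and 3 adjusted over the list alone), macrophage markers (0.113) and kidney and adrenal markers (0.093) went up, the macrophage median reaching 0 under median scaling.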
